A study of Mus musculus with 10 samples.

How the data were processed

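RNA was measured in RAW264.7 cells, a mouse macrophage-like line, on 10 single-channel arrays in 5 groups of 2: EtoH, Dex (dexamethasone), FF (fluticasone furoate), VSG22 and VSGC12. Per the labels, a glucocorticoid was added at 100 nM, followed 1 hour later by lipopolysaccharide (LPS, a bacterial cell-wall component that activates macrophages) at 1 µg/ml, and RNA was taken at 16 hours. Labelling started from 150 ng of RNA. The labels do not say whether the EtoH cells were given LPS, so EtoH is read here as solvent without glucocorticoid, and this limit applies to each comparison with it. No group is described as unstimulated. The labels also do not say whether the replicates came from separate cultures.

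Per the file headers, each file holds the output of Agilent Feature Extraction 10.7.3.1 in the unit intensity: the spot's mean signal, its local background, and a processed signal with background subtracted and spatial trends removed within the array. The deposited files are not scaled between arrays. They also carry other columns, flags set by the software for spots well above background, saturated, non-uniform or outlying. The submitters list limma without naming the step it was used for. Each array holds 62976 spots, of which 59305 are not controls, and these carry 55681 distinct probes. Between 40.1% and 44.4% of the spots that are not controls were well above background, and 0 were saturated. The number of arrays limits the precision.

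Spots marked non-uniform or outlying were left out, and the log2 processed signals of a probe's spots were averaged. A probe counted as well above background on an array where over 0.5 of its spots were. A gene counted as such on an array where any of its probes did, including probes other than the one that represents it. From each array its own 75th percentile over probes that are not controls was subtracted. Probes were named from the mouse gene table of GRCm38.p6, used for names only: 26413 by their accession, 3859 by symbol and 735 by a synonym, and 24674 kept the name in the file. Probe positions are those in the files, on mm9, and no mm9 annotation was at hand to place them in exons or untranslated regions. A gene was represented by the probe with the highest mean over the 10 arrays among probes that were well above background on every array of at least 1 group. This left 18051 genes, of which 11819 carry a current symbol; 138 lack a value on some array, so the number tested varies slightly by comparison. Of the 4085 genes with more than 1 measured probe, 128 had probes called in opposite directions.

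The groups were fitted together with limma 3.58.1 (R 4.3.3, lmFit and eBayes, group as the only term; 5 residual and 1.82 prior degrees of freedom). Each glucocorticoid was compared with EtoH, the mean of the 4 with EtoH, and each pair of glucocorticoids with each other; a moderated F-test compared the 4. Tests were two-sided and adjusted over genes by Benjamini and Hochberg within a comparison, with a threshold of 0.05. Intervals are 95% intervals from the same fit. Where a gene was not well above background on any array of a group, its fold is given as at least the ratio to the lowest signal that counted as well above background on those arrays. The replicate number follows the 2 slides, each holding all 5 groups. Deviations from the group mean correlated between groups by slide with r from -0.03 to 0.33 across genes, which are not independent replicates. The highest were 0.33 (Dex and VSGC12), 0.31 (FF and VSGC12) and 0.27 (Dex and FF). No block was fitted in the main processing. A replicate block is among the alternatives, and values within slides are given beside the response sizes.

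Before the data were examined, the main processing, the comparisons, 27 gene lists, the alternative settings and the rule for named genes were fixed. The lists cover glucocorticoid receptor-induced genes, phagocytic and alternative-activation genes, pro-inflammatory cytokines, chemokines, inflammatory enzymes and effectors, the NF-kB pathway, the type I interferon response, antigen presentation, MAP kinase phosphatases and mRNA-decay factors, JAK-STAT feedback, glycolysis and hypoxia, sterol synthesis, lipid handling, cell cycle, osteoclast genes, oxidative stress, unfolded protein stress, the circadian clock, the receptor and its cofactors, the mitochondrial respiratory chain, macrophage identity, markers of 5 other cell types and reference genes. The 22 lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, with camera and an estimated correlation, and with fry; p-values were adjusted over the lists within a comparison. Named genes are the 10 highest and 10 lowest for the mean of the 4 (all 8 treated arrays on one side of both EtoH arrays, detected in every group, with a symbol), up to 4 members per list, the 3 highest and 3 lowest per glucocorticoid not already named (limited to genes well above background on at least 1 array of EtoH and of that group, which the rule as first written did not ask for), the 5 highest and 5 lowest per pair, 14 genes named in advance, and up to 3 higher and 3 lower genes with the largest bound. The rule gave 153 genes, of which 4 are not reported here, and a gene named outside it is marked as chosen after its values were seen.

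Alternatives planned in advance were normexp background correction (offset 50), quantile normalization, subtracting the array median, no filter on dim probes, a filter requiring all 10 arrays, the mean of a gene's probes, a replicate block, eBayes with trend and robust, fitting only the groups compared, an estimated correlation in camera, and leaving out each array in turn. A further 5 were added after seeing the data: leaving out probes in patches of local signal, a 75th percentile over detected probes, quantile normalization followed by cyclic loess, the mean without both Dex arrays, and leaving out each Dex array with the gene set held fixed. The procedure was tested on simulated data: for the mean of the 4, 61.2% of genes changed 1.5-fold, 79.1% changed 2-fold and 97% changed 4-fold were called when 200 of 17913 genes were changed, and 16 unchanged genes were called beside them. For VSGC12 against VSG22 the shares were 16.4%, 68.7% and 95.5%, with 12 unchanged genes called. The simulation gave all groups the same spread and capped the widest spreads. Replicates differed more in Dex (SD of the difference 0.63) than elsewhere (0.33 to 0.41), so these shares do not describe tests with Dex. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, the data.table package in version 1.17.8 and statmod 1.5.0 were also used.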

Results

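Gene expression was measured in RAW264.7 cells, a mouse macrophage-like line, with 2 arrays for each of 5 groups. Dex and FF are synthetic glucocorticoids in clinical use, and VSG22 and VSGC12 are glucocorticoids known here only by their code names. Each was given at 100 nM, 1 hour before LPS, and RNA was taken at 16 hours. The EtoH group is read as solvent without glucocorticoid, since the labels do not state whether it received LPS. The array 75th percentile of processed signal ran from 375.1 in EtoH replicate 1 to 536.8 in Dex replicate 2. Replicates correlated across genes with r between 0.983 in Dex and 0.995 in EtoH and VSG22, and genes are not independent replicates. The SD of the difference between replicates was 0.63 in Dex and between 0.33 and 0.41 in the other groups. The first principal component held 46.8% of the variance and placed the EtoH arrays at -71.1 and -69.5 and the 8 glucocorticoid arrays between 0 and 37.5, with the Dex arrays at those ends.

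The mean of the 4 glucocorticoids against EtoH asks what glucocorticoids as a class do to these cells. At camera's preset correlation, lists of cell cycle genes were higher in the glucocorticoid groups and those of interferon and cytokine genes lower, while 0 lists were called with an estimated correlation (adjusted p = 0.2, 0.31 and 0.066). Of 18030 genes tested, 7961 (44.2%) changed, 3893 upward and 4068 downward, and 838 rose and 597 fell at least 2-fold. At an unadjusted p under 0.05 there were 9504. Hp (probe at chromosome 8, 112099045 to 112099104), which encodes the haemoglobin-binding protein haptoglobin, rose 32.1-fold (log2 5.00 ± 0.08, SE, 8 arrays against 2, adjusted p = 1.5e-06), from a log2 signal of -2.44 ± 0.06 (SD, n = 2) relative to the array's 75th percentile in EtoH. Il33 (chromosome 19, 30035101 to 30035160), an interleukin-1 family cytokine, was 28.5-fold lower (log2 -4.83 ± 0.22, adjusted p = 1.7e-05). Ccna2 (chromosome 3, 36463978 to 36464037), the cyclin of DNA replication and early mitosis, rose 24.5-fold (log2 4.61 ± 0.15, adjusted p = 5.5e-06). The mitotic kinase genes Pbk and Plk1 rose by log2 4.96 and 4.09, the nuclease genes Exo1 and Ankle1 by 3.94 and 4.06, and the spindle gene Aspm by 3.90. Lrr1 (4.65), the transcription factor gene E2f7 (3.85) and the metalloreductase-family gene Steap1 (3.8) complete the highest 10. Among these, the probes of Pbk, Plk1 and Exo1 lie in a patch of local signal on a Dex array. A spot was in a patch if at least 3 of the 24 spots around it were well above background only in that group. The spot's own signal was not used, so a probe in a patch need not carry stray signal. Of 18051 genes tested, 1498 (8.3%) have a probe in a patch on a Dex array. Patches on other arrays are not marked for single genes. Over the alternatives the log2 change ran from 1.46 to 4.06 for E2f7, 2.22 to 4.29 for Aspm and 2.76 to 5.06 for Lrr1. Their calls were kept in each setting that tested them. The antiviral genes Mx1 (chromosome 16, 97668644 to 97668703) and Rsad2 (chromosome 12, 27127859 to 27127918) fell by 3.93 ± 0.10 and 3.65 ± 0.07. The interferon-induced genes Cmpk2 and Ifit2 fell by 3.38 and 3.35. The chaperone gene Clu (-3.21), Tent5c (-3.10), Pakap (-2.90), the chemokine gene Ccl12 (-2.84) and the lipid phosphatase gene Plpp3 (-2.84) were the others among the lowest 10. Some genes were not well above background on either EtoH array. Of these, Depdc1b was at least 9.71-fold higher, Serpina3g at least 9.15-fold, Arl14epl at least 6.12-fold and Cfap69 at least 3.43-fold. In the other direction, Rhov was at least 4.79-fold lower, with a probe in a patch on a Dex array, Col23a1 at least 3.79-fold and Rtn4r at least 3.75-fold.

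The counts of this comparison depend on the EtoH arrays and on scaling: 4899 genes were called without EtoH replicate 1, 4734 without EtoH replicate 2, and 4935 with no filter on dim probes. Subtracting the array median, which moves the median of all genes from -0.005 to 0.118, gave 3763 genes, 70.2% of them higher, against 48.9% in the main processing. The share was 43.8% with quantile normalization and 39.2% with a percentile over detected probes, so it is tied to the scale chosen. Calls of named genes lost with the array median subtracted include those of Ripk2, Cd40, Nlrc5, Ncoa1, Il10, Sbno2, Oscar, Dcstamp, Ep300, Ndufa4, Hprt, Ppia and Ywhaz. Calls lost with no filter include those of Oscar, Dcstamp, Ep300, Ndufa4, Hprt, Ppia, Ywhaz, Cd4, Elane, Camp, Per1, Tnf and Ccl2, and with normexp those of Oscar, Fasn, Tpsb2 and Camp. Without both Dex arrays 8502 genes were called.

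**Figure D1:**
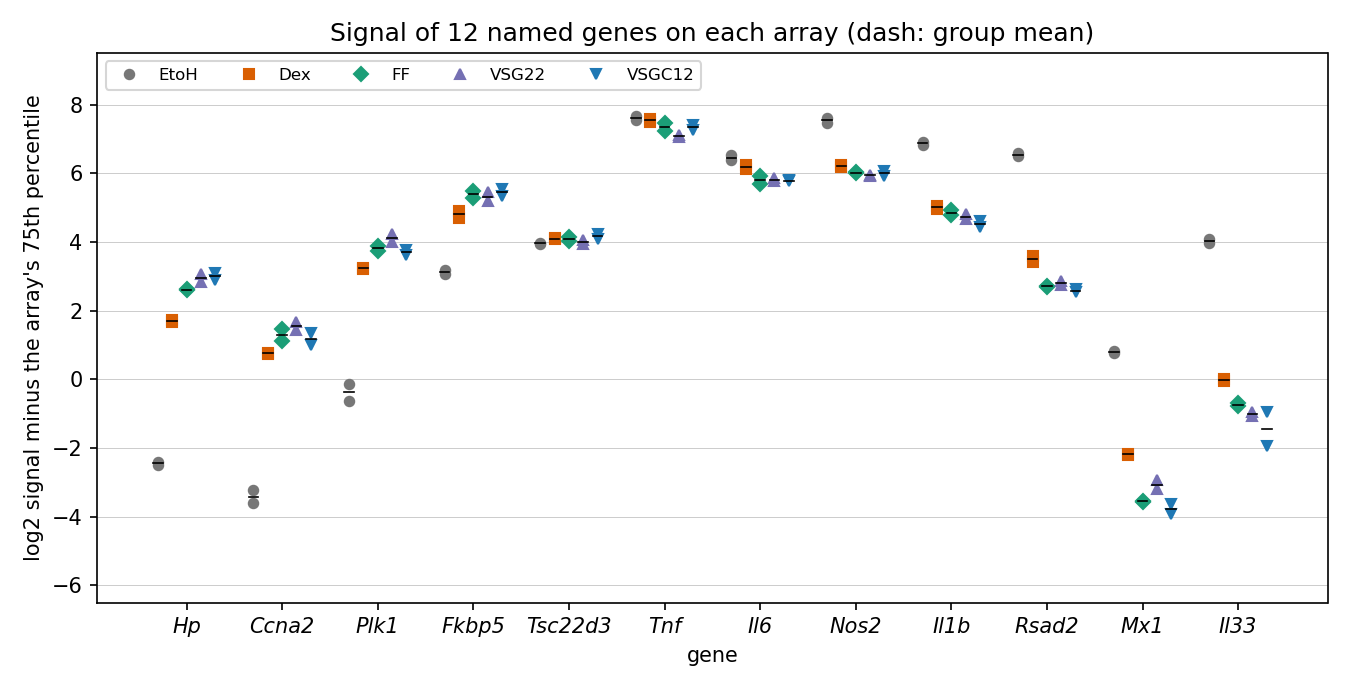
Signal (log2, minus the array's 75th percentile) of 12 named genes on each array; each marker is 1 array, the dash is the group mean, and colours and shapes give the group. Hp, Ccna2 and Plk1 lie higher, and Rsad2, Mx1 and Il33 lower, on all 8 glucocorticoid arrays than on both EtoH arrays.

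Interferon, cytokine and chemokine genes fell. Ccl3, Cdt1, Insig1, Arntl and Dusp2 were chosen after their values were seen, as exceptions within their lists. Of 36 measured genes of the type I interferon list, 24 fell and 0 rose (adjusted over the list alone, 25 fell and 1 rose), with a mean log2 change of -0.97 (camera adjusted p = 5.3e-08; adjusted p = 0.31 with an estimated correlation). Of 21 pro-inflammatory cytokine genes, 18 fell and 0 rose (adjusted over the list alone, 18 fell and 1 rose), with a mean of -1.10 (adjusted p = 4.9e-07; adjusted p = 0.066 with an estimated correlation). Ifnb1, which encodes interferon beta, was at least 3.21-fold lower, and Inhba, a subunit of activin, at least 1.54-fold lower. Il1b fell by 2.09 ± 0.08 on the log2 scale (adjusted p = 1.1e-05; its probe lies in a patch on a Dex array), and Il6 by 0.56 ± 0.08 (adjusted p = 0.002; not called when the array median was subtracted, -0.44). Tnf was -0.28 ± 0.09 (adjusted p = 0.037), with a probe in a patch on a Dex array, and its call was lost in 9 of 23 alternatives. These include leaving out EtoH replicate 1 (-0.34) or replicate 2 (-0.22), Dex replicate 1 (-0.27), VSG22 replicate 1 (-0.27) or replicate 2 (-0.29), or VSGC12 replicate 1 (-0.26). Of 15 chemokine genes, 8 fell and 1 rose, with a mean of -0.58 (adjusted p = 0.013; adjusted p = 0.31 with an estimated correlation). The counts were the same adjusted over the list alone. The monocyte attractants Ccl12, Ccl7 and Ccl5 fell by 2.84, 2.01 and 1.23, Cxcl10 by 0.72 and Ccl2 by 0.38 ± 0.08, while Ccl3 rose by 0.30. The call of Ccl2 was lost in 3 of 24 alternatives, including without EtoH replicate 1 (-0.28). On the glucocorticoid arrays, all from cells given LPS, the cytokine list mean was -0.89 to -1.23 relative to EtoH. The interferon list mean was -0.65 to -1.17. For these 2 lists, lower values in cells given LPS argue against EtoH cells without LPS, which the labels leave open.

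The other inflammation lists moved both ways. Of 28 genes for inflammatory enzymes and effectors, 12 rose and 9 fell (13 and 9 adjusted over the list alone; list adjusted p = 0.29). Nos2, the inducible nitric oxide synthase (chromosome 11, 78773567 to 78773626), fell by 1.49 ± 0.07 (adjusted p = 2e-05) and Ptgs2, inducible cyclooxygenase, by 1.22 ± 0.10. The collagenase gene Mmp13 fell by 2.62 and complement factor B, Cfb, by 1.69, while the endothelin gene Edn1 rose by 1.98 and the arginine transporter gene Slc7a2 was at least 3.41-fold higher. Of 27 NF-kB pathway genes, 6 rose and 9 fell (7 and 9 adjusted over the list alone; list adjusted p = 0.89), with a median of 0.03 and a mean of 0.00 where camera's direction was down. Irak3, a brake on Toll-like receptor signalling, rose by 0.99 and Nfkb1 by 0.65, while Traf1 fell by 0.80 and Ripk2 by 0.68. Of 19 genes for antigen presentation and co-stimulation, 3 rose and 9 fell, adjusted over the list alone as well (list adjusted p = 0.099). Cd83 fell by 1.20, Cd40 by 0.67 and Nlrc5 by 0.59, and Icosl rose by 0.70. Of 18 JAK-STAT feedback and anti-inflammatory genes, 1 rose and 5 fell, also when adjusted over the list alone (list adjusted p = 0.22). The phosphatase gene Ptpn1 rose by 0.81, and the interleukin-1 receptor antagonist gene Il1rn fell by 1.23, Cish by 0.72 and Sbno2 by 0.53 (not called without EtoH replicate 2, -0.50). Il10, which is not on this list, fell by 0.56 ± 0.06. Of 14 phagocytic and alternative-activation genes, 3 rose and 5 fell, with equal counts adjusted over the list alone (list adjusted p = 0.67). The efferocytosis receptor gene Mertk was at least 4.59-fold higher and the mannose receptor gene Mrc1 at least 1.65-fold lower, and Thbs1 fell by 1.44 and Gas6, which encodes a ligand of Mertk, by 1.34.

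Cell cycle genes rose almost as a whole. Of 30 measured, 28 rose and 1, the replication licensing factor Cdt1 (-0.51), fell, with a mean of 1.80 (camera adjusted p = 2.9e-17; adjusted p = 0.2 with an estimated correlation). The counts were the same adjusted over the list alone. The survivin gene Birc5 rose by 3.35 ± 0.10 and the ribonucleotide reductase gene Rrm2 by 3.27 ± 0.12. Of 21 sterol synthesis and uptake genes, 14 rose and 1, Insig1 (-0.71), fell, adjusted over the list alone too, with a mean of 0.44 (adjusted p = 9.2e-05; adjusted p = 0.31 with an estimated correlation). Idi1 rose by 1.07, Hsd17b7 by 1.03 and Cyp51 by 0.90, all enzymes of cholesterol synthesis. Of 27 genes of the mitochondrial respiratory chain, 18 rose and 0 fell (19 and 0 adjusted over the list alone), by a small mean of 0.29 (adjusted p = 4.3e-05; adjusted p = 0.31 with an estimated correlation), with Sdhc at 0.69 (not called without probes in patches, 0.17) and Cox5b and Ndufv1 at 0.58. Ndufa4 was 0.56 and was not called without EtoH replicate 1 (0.60) or replicate 2 (0.52). Of 23 lipid handling genes, 8 rose and 11 fell, adjusted over the list alone as well (list adjusted p = 0.67), and the median was -0.05 where the mean was 0.06. The lipase gene Lpl rose by 1.74, the desaturase gene Scd1 by 1.48 (probe in a patch on a Dex array), and Fabp4 by 1.29. Fasn was at least 1.06-fold higher, a call lost without EtoH replicate 2 (log2 0.82). Of 24 glycolysis and hypoxia genes, 3 rose and 10 fell, equally so adjusted over the list alone (list adjusted p = 0.065; called without EtoH replicate 1, -0.29, or VSGC12 replicate 1, -0.28). Among those that fell were Ndrg1 (-1.33), Adm (-1.28), Hk3 (-1.23) and Ero1a (-0.88).

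Genes known as direct glucocorticoid targets were mixed. Of 21 measured, 5 rose and 4 fell, adjusted over the list alone too (list adjusted p = 0.88), with a median of 0.05 and a mean of -0.03 where camera's direction was up and fry's down. Fkbp5, a co-chaperone of the glucocorticoid receptor (chromosome 17, 28536060 to 28536119), rose by 2.11 ± 0.10 (adjusted p = 2.3e-05) and Angptl4 by 1.17, while Rgs2 fell by 2.38 and Ddit4 by 1.54. Tsc22d3, which encodes the anti-inflammatory protein GILZ, was 0.13 ± 0.07 (adjusted p = 0.17), Dusp1 0.06 ± 0.13 (adjusted p = 0.73), Zbtb16 -0.36 ± 0.39 (adjusted p = 0.47) and the receptor gene Nr3c1 -0.15 ± 0.07 (adjusted p = 0.14). Nr3c1 was called with the mean of its probes and with a percentile over detected probes, and ran from -0.44 to -0.03 over the alternatives. The clock gene Per1 was -0.37 ± 0.12 (adjusted p = 0.04), a call lost in 12 of 24 alternatives. These include leaving out EtoH replicate 1 (-0.42) or replicate 2 (-0.33), Dex replicate 1 (-0.37) or replicate 2 (-0.38), FF replicate 2 (-0.35), or VSG22 replicate 1 (-0.39) or replicate 2 (-0.36). Of 16 genes for the receptor and its cofactors, 3 rose and 3 fell, adjusted over the list alone as well (list adjusted p = 0.69). The co-chaperone gene Fkbp4 rose by 1.08, and Hsp90aa1 fell by 1.10, Ncoa1 by 0.63 and Ep300 by 0.47 (not called without EtoH replicate 1, -0.45, or replicate 2, -0.48). Of 12 circadian clock genes, 10 fell and 1, Arntl (0.23), rose, also adjusted over the list alone, with a mean of -1.03 (adjusted p = 0.00069; adjusted p = 0.31 with an estimated correlation). Tef fell by 2.0, Bhlhe40 by 1.80, Nr1d2 by 1.75 (not called without EtoH replicate 2, -1.42) and Bhlhe41 by 1.43. Of 14 MAP kinase phosphatase and mRNA-decay genes, 7 fell and 1, Dusp2 (1.18), rose, adjusted over the list alone too, with a mean of -0.53 (adjusted p = 0.039; adjusted p = 0.38 with an estimated correlation). Dusp14 fell by 2.07, Dusp10 by 1.96, Dusp5 by 1.54 and Dusp8 by 1.44. That list's call was lost without EtoH replicate 2 (-0.49), Dex replicate 1 (-0.52) or VSGC12 replicate 2 (-0.52), without Dex replicate 2 with the gene set held fixed (-0.54), without probes in patches (-0.41) and without both Dex arrays (-0.57).

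Of 14 osteoclast-associated genes, 9 fell and 0 rose, adjusted over the list alone as well, with a mean of -0.43 (adjusted p = 0.0062; adjusted p = 0.31 with an estimated correlation). Atp6v0d2 fell by 1.96 (probe in a patch on a Dex array), Oscar and Tcirg1 by 0.79 and Dcstamp by 0.71. The calls of Oscar and Dcstamp were lost without EtoH replicate 1 (-0.67 and -0.80) and without replicate 2 (-0.90 and -0.62). Of 18 oxidative stress genes, 4 rose and 5 fell, adjusted over the list alone too (list adjusted p = 0.7), with a median of 0.06 and a mean of -0.14. Hmox1, haem oxygenase 1, fell by 1.86, Sqstm1 by 1.04 and Srxn1 by 0.92, and Gsr rose by 0.89. Of 20 unfolded protein and amino-acid stress genes, 2 rose and 4 fell, equally so adjusted over the list alone (list adjusted p = 0.5). Atf3 fell by 1.62, Dnajb9 by 0.89 and Ddit3 by 0.74, and Mthfd2 rose by 0.79. Of 21 macrophage identity genes, 5 rose and 7 fell, adjusted over the list alone as well (list adjusted p = 0.67). Itgam rose by 1.29, Csf1r by 1.18 and Lyz2 by 0.94. Markers of other cells were few: 0 epithelial and 0 B cell markers were measured, too few to test. Of 2 fibroblast markers, Lum was 0.57 ± 0.21 (adjusted p = 0.067, probe in a patch on a Dex array; called without Dex replicate 1, 0.47, or replicate 2, 0.67) and Dcn -0.01 ± 0.36 (adjusted p = 0.99). Of 4 T cell markers, Cd4 rose by 1.23 (adjusted p = 0.024; not called without EtoH replicate 1, 1.19, or replicate 2, 1.28) and Il7r fell by 1.51. Of 3 neutrophil and mast cell markers, Tpsb2 was 0.57 (not called with normexp, 0.20), Elane 1.12 (adjusted p = 0.044) and Camp -0.52 (adjusted p = 0.025). The call of Elane was lost in 11 of 24 alternatives, including without any 1 of the EtoH (0.93 and 1.31), FF, VSG22 and VSGC12 arrays, and that of Camp in 7, including without EtoH replicate 1 (-0.28) and FF replicate 1 (-0.52). Of 12 commonly used reference genes, 6 rose and 0 fell, adjusted over the list alone as well (list adjusted p = 0.14, mean 0.16, same sign under each scaling). Tfrc rose by 0.61 (not called with the mean of its probes, 0.28), Hprt by 0.35 (probe in a patch on a Dex array), Ppia by 0.27 and Ywhaz by 0.35. Ywhaz was -0.02 with the mean of its probes and was not called without EtoH replicate 1 (0.19), FF replicate 1 (0.33) or either VSG22 array (0.35). The calls of Hprt and Ppia were lost without EtoH replicate 1 (0.32) and replicate 2 (0.21) respectively, and that of Ppia in 6 of 24 alternatives, with a lowest value of 0.13.

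**Figure D2:**
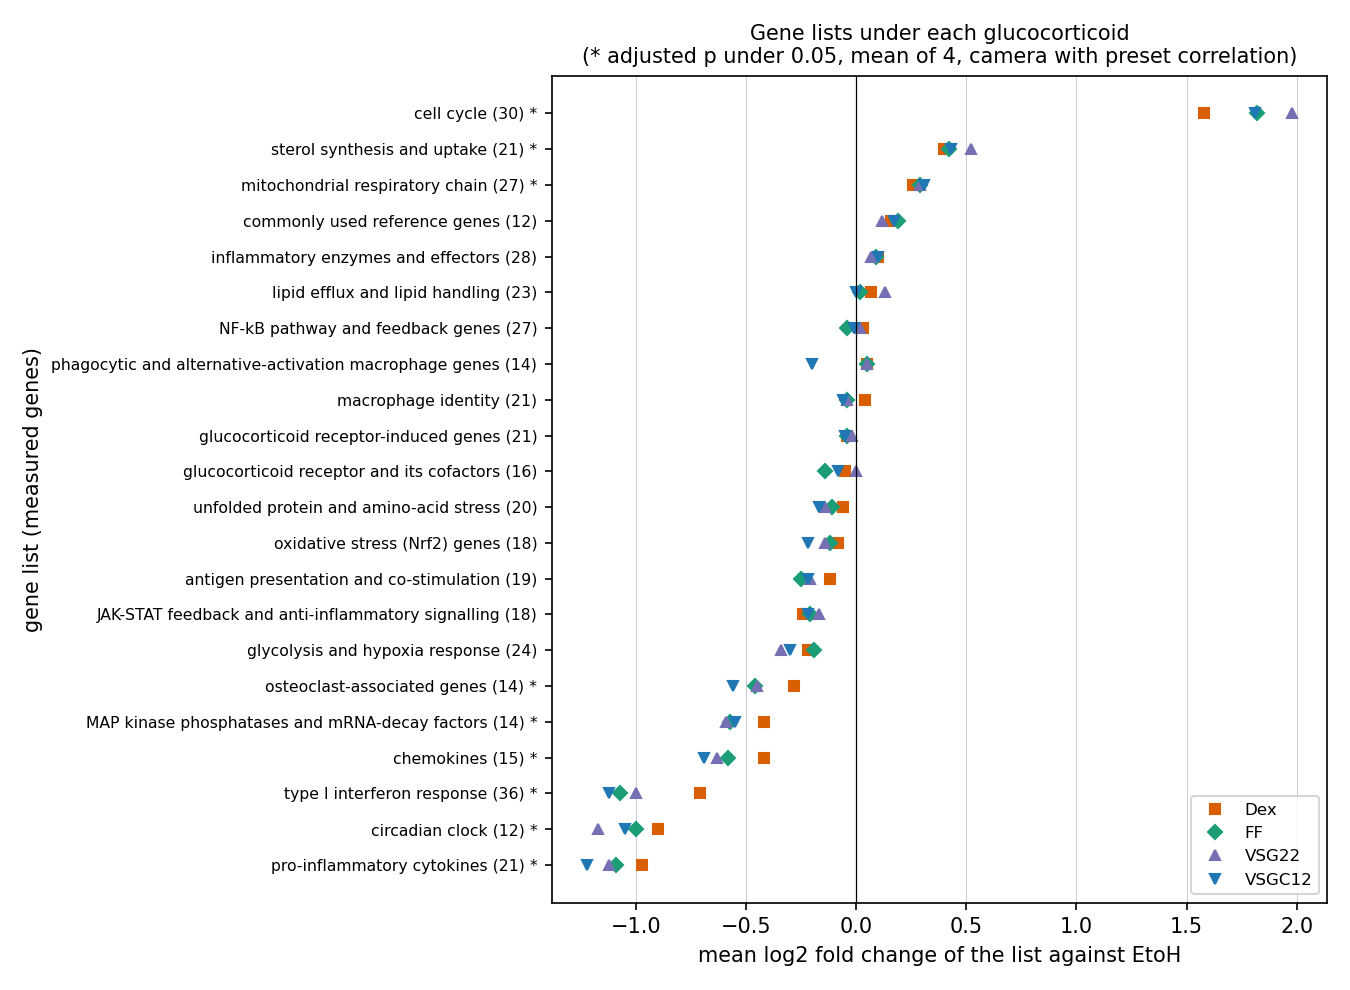
Mean log2 fold change against EtoH of the 22 tested gene lists under each glucocorticoid; markers are the glucocorticoids, numbers in parentheses are measured genes, and a star marks an adjusted p under 0.05 for the mean of the 4 with camera's preset correlation. Cell cycle genes lie highest, between 1.58 and 1.98, and cytokine genes lowest, between -0.97 and -1.22.

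Each glucocorticoid on its own was compared with EtoH to see which genes it changes. Each raised cell cycle genes and lowered interferon and cytokine genes at camera's preset correlation, while 0 lists were called for any of them with an estimated correlation (adjusted p between 0.052 and 0.53). Genes called were 5837 for Dex (2989 up, 2848 down), 6693 for FF (3233 and 3460), 5528 for VSG22 (2903 and 2625) and 6414 for VSGC12 (3096 and 3318). The split turned with the scale: 1411 and 632, 1715 and 782, 1233 and 573, and 1685 and 679 with the array median. With a percentile over detected probes it was 2445 and 3845, 2669 and 4231, 2505 and 3027, and 2595 and 3930. All 4 raised 1980 of the same genes and lowered 1824, counts that the shared EtoH arrays alone would raise and that were not simulated. The mean of the cell cycle list was 1.58 in Dex, 1.82 in FF, 1.98 in VSG22 and 1.81 in VSGC12, and that of the interferon list -0.71, -1.07, -1.0 and -1.12. Camera called 9 lists for Dex and 10 for each other glucocorticoid. The additional list was antigen presentation for FF (mean -0.25, adjusted p = 0.043), and glycolysis and hypoxia for VSG22 (-0.34, adjusted p = 0.0094) and for VSGC12 (-0.30, adjusted p = 0.041). Hp rose by 4.14 in Dex, 5.05 in FF, 5.38 in VSG22 and 5.44 in VSGC12 (SE 0.11 each), and Fkbp5 by 1.69, 2.26, 2.19 and 2.31 (SE 0.13 each).

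Among genes well above background on at least 1 array of EtoH and of the glucocorticoid, and beyond those named for the mean, the changes below were among the largest. Pik3c2g (7.14 ± 0.58), the copper chaperone gene Cox17 (3.77 ± 0.65) and Tgif2lx2 (3.66 ± 0.89) rose most in Dex, and Gstt4 (-3.61 ± 0.65), Osbp2 (-3.33 ± 0.33) and Gatad2b (-2.80 ± 0.75) fell most. The probe of Pik3c2g lies in a patch on a Dex array, and with no filter, where another probe represents the gene, it was -0.25. The values of Pik3c2g in Dex and in VSGC12 each rest on replicate 2 alone. The gene also lacks a value in some group, so it was not tested on the mean contrast. Tgif2lx2 was not called without EtoH replicate 2 (2.69) or Dex replicate 2 (2.91), and Gatad2b not without any 1 of the arrays of the other groups (-2.77 to -2.84). In FF, Vmn2r-ps38 (3.97 ± 1.26) and the thymidine kinase gene Tk1 (3.79 ± 0.10) were among those that rose most, Vmn2r-ps38 with a call lost without any 1 array outside Dex (3.20 to 4.74), and the secretogranin gene Scg2 (-3.07) and the interferon-induced genes Ifit3b (-3.06) and Ifit3 (-3.01) fell most. In VSG22, the DNA repair genes Fanci (4.14) and Rad54l (3.90) and Sapcd2 (4.02) rose most, and Scg2 (-3.38), Pdpn (-3.12) and Mylk2 (-3.07) fell most. In VSGC12, Pik3c2g (4.61; -0.03 with no filter), Fanci (3.77) and Sapcd2 (3.71) rose most, and Ifit3b (-3.39), the collagen gene Col5a3 (-3.25) and Ifit3 (-3.24) fell most. The probes of Ifit3b, Ifit3 and Rad54l also lie in a patch on a Dex array. Leaving out an array changed these counts: without EtoH replicate 1 and replicate 2 they were 3131 and 3242 for Dex, 4313 and 3934 for FF, 3536 and 3380 for VSG22, and 4127 and 3783 for VSGC12. Dropping FF replicate 1 gave 4356 for FF, VSG22 replicate 1 and replicate 2 gave 2982 and 3232 for VSG22, VSGC12 replicate 2 gave 4197 for VSGC12, and Dex replicate 2 with the gene set held fixed gave 3715 for Dex.

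Dex was compared with the other glucocorticoids to see whether they differ at one dose and time. The spread was pooled over all groups, although replicates differed more in Dex (SD of the difference 0.63) than elsewhere (0.33 to 0.41). Tests with Dex therefore rest on a spread that is small for Dex. Hp was higher in FF, VSG22 and VSGC12 than in Dex, and at camera's preset correlation the interferon list was lower and the cell cycle list higher, while 0 lists were called with an estimated correlation (adjusted p = 0.35 to 0.49). Between FF and Dex 67 genes differed (14 higher and 53 lower in FF), between VSG22 and Dex 99 (35 and 64), and between VSGC12 and Dex 71 (11 and 60), with 2603, 3017 and 2680 genes at an unadjusted p under 0.05. With the replicate number, which is also the slide, as a block they were 31, 118 and 48. With no filter they were 3, 5 and 5, with the filter over all 10 arrays 0, 5 and 18, and with only the groups compared 0, 0 and 0. Of the 79 genes called higher in Dex than in another glucocorticoid, at least 40 passed the main filter only through the Dex arrays. These 40 were not well above background on any array of the other groups. Hp was higher than in Dex by 0.90 in FF (95% interval 0.65 to 1.16, adjusted p = 0.033), 1.24 in VSG22 (0.99 to 1.49, adjusted p = 0.014) and 1.29 in VSGC12 (1.04 to 1.55, adjusted p = 0.019). Mx1 was lower in FF by log2 -1.37 (-1.66 to -1.08, adjusted p = 0.016). Ifit2 was lower by -1.15 in FF and -0.91 in VSG22, and Ifit3b, with its probe in a patch on a Dex array, by -1.30 in FF, -1.23 in VSG22 and -1.63 in VSGC12. The guanylate-binding protein gene Gbp3 was lower in FF (-0.89), Ccl7 in VSG22 (-0.89), and Ccl12 (-1.69) and Col5a3 (-1.60) in VSGC12. Asb11, whose probe lies in a patch on both Dex arrays, was lower in all of them (-1.84, -1.70 and -1.69), as were Tmprss3 in VSG22 (-0.96) and Scarf1 in VSGC12 (-1.79, probe in a patch on a Dex array). Among genes higher than in Dex were Cep295 (1.61), Serpina3g (1.58) and Psd4 (1.52) in VSG22, and Zfp101 (0.82 and 0.81), Cfap69 (0.72 and 0.93) and the glutathione transferase gene Mgst2 (0.50 and 0.59) in FF and VSGC12. Each of these calls was lost with no filter on dim probes, and without at least 1 array outside Dex, though the estimate moves only with the arrays compared. With the replicate block, calls were lost for Hp, Ifit3b, Zfp101, Cfap69, Mgst2 and Gbp3 in FF, Cep295 and Tmprss3 in VSG22, and Ccl12 and Zfp101 in VSGC12. Hp was not called for FF without any 1 array outside Dex (0.90 or 0.91), nor for VSG22 and VSGC12 without any 1 EtoH or FF array (1.24 and 1.29), and Mx1 not without EtoH replicate 2 (-1.37).

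Of the interferon list, 4 genes were lower in FF than in Dex (13 adjusted over the list alone), 4 in VSG22 (10) and 5 in VSGC12 (17), and 0 were higher. The list mean differed by -0.37 (camera adjusted p = 2.2e-11; adjusted p = 0.49 with an estimated correlation), -0.29 (1e-08; adjusted p = 0.35 with an estimated correlation) and -0.41 (2.3e-12; adjusted p = 0.37 with an estimated correlation). The cell cycle list differed by 0.24 in FF, 0.40 in VSG22 (1 gene higher, 25 higher and 1 lower adjusted over the list alone) and 0.23 in VSGC12 (camera adjusted p = 3.2e-08, 2.1e-14 and 1.5e-07; adjusted p = 0.49, 0.35 and 0.4 with an estimated correlation). Of 132 tests of a list in a pair of glucocorticoids, camera called 25, of which 16 were in pairs with Dex, and 0 with an estimated correlation. The others with Dex were antigen presentation in FF (-0.14), and cytokines (-0.15), chemokines (-0.21) and glycolysis (-0.12) in VSG22. In VSGC12 they were phagocytic genes (-0.25), cytokines (-0.25), chemokines (-0.27), lipid handling (-0.08), osteoclast genes (-0.28) and unfolded protein stress (-0.11), each at an adjusted p of 0.35 or more with an estimated correlation. Apart from interferon and cell cycle, each of these list calls was lost without Dex replicate 1 when the filter was applied anew, and the lists called fell from 5 to 2 for VSG22 and from 8 to 2 for VSGC12. With the gene set held fixed they fell to 4 and 4 without either Dex array. Without Dex replicate 2 they were 2 and 3, without VSG22 replicate 2 there were 3 for VSG22, and without VSGC12 replicate 2 there were 5 for VSGC12. A left-out array changes the pooled spread, the genes that pass the filter and, for the groups compared, the estimate itself. The gene counts turned on single arrays, and which of these moved them was not tested. Without Dex replicate 1 or replicate 2 they were 880 and 820 for FF, 1856 and 723 for VSG22, and 1233 and 703 for VSGC12. With the gene set held fixed they were 263 and 226, 1224 and 224, and 587 and 218. Without EtoH replicate 1 or replicate 2 they were 26 and 22, 16 and 10, and 5 and 5. For FF, 155 genes differed without FF replicate 2, 25 and 24 without VSG22 replicate 1 and replicate 2, and 23 and 22 without VSGC12 replicate 1 and replicate 2. For VSG22, the counts were 17 and 16 without FF replicate 1 and replicate 2, 58 and 41 without its own, and 32 and 34 without those of VSGC12. For VSGC12, they were 6 and 7 without those of FF, and 17 and 14 without those of VSG22.

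**Figure D3:**
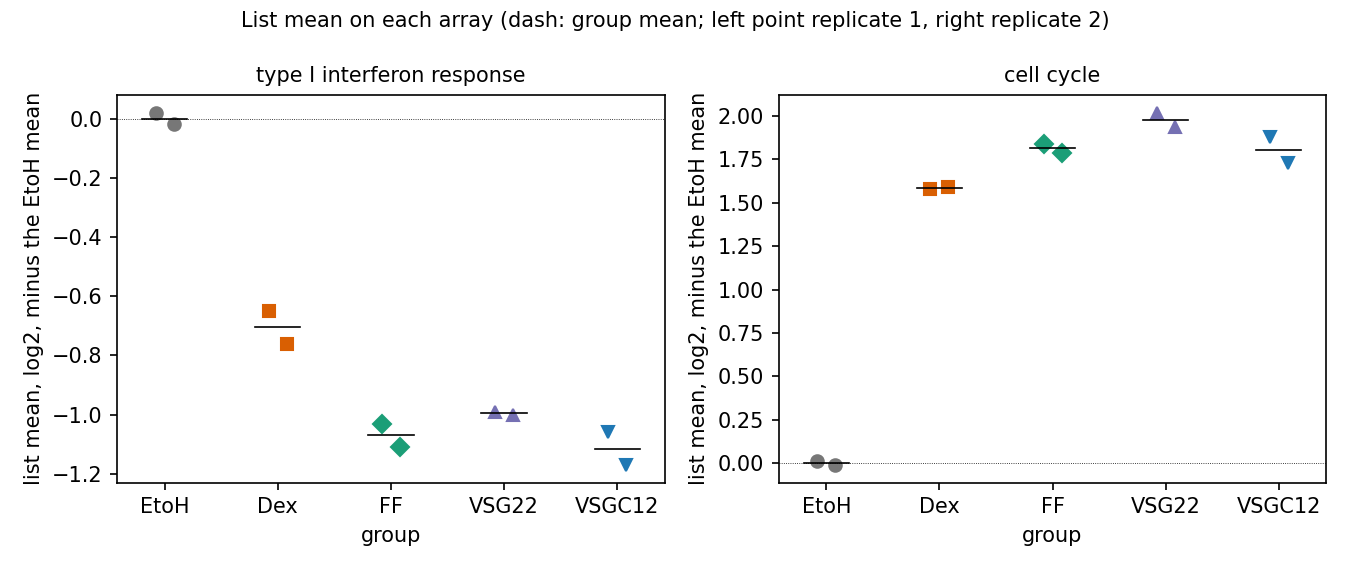
Mean log2 value of the type I interferon list (left) and the cell cycle list (right) on each array, minus the EtoH mean; the left point of a group is replicate 1, the right one replicate 2, and the dash is the group mean. The Dex arrays lie at -0.65 and -0.76 for interferon genes, above the other glucocorticoid arrays at -0.99 to -1.17.

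The remaining pairs compare FF, VSG22 and VSGC12 with each other. Few genes separated them. The spread was pooled over all groups, and replicates differed more in Dex, so it is wide for these pairs. With only the groups compared, where fewer arrays gave the spread, 0 genes were called in each pair. Between VSGC12 and FF 1 gene passed the test: Pign (chromosome 1, 107418310 to 107418369), an enzyme of membrane-anchor synthesis, was lower in VSGC12 by log2 -2.14 (95% interval -2.44 to -1.84, adjusted p = 0.013). Its call was lost with a replicate block, with no filter and without EtoH replicate 2 (-2.14 in each), and with the mean of its probes (-0.98). Limma called 0 genes between VSGC12 and VSG22 and 0 between FF and VSG22, with 1290 and 1708 at an unadjusted p under 0.05 (763 for VSGC12 and FF). Hp differed by 0.05 between VSGC12 and VSG22 (-0.20 to 0.31) and by 0.39 between VSGC12 and FF (0.13 to 0.64, adjusted p = 0.99). Il1b differed by -0.21 (-0.46 to 0.04) and -0.33 (-0.58 to -0.07, adjusted p = 0.99) in the same pairs. Nos2 differed by 0.06 (-0.15 to 0.27) and -0.03 (-0.24 to 0.19), and Fkbp5 by 0.12 (-0.19 to 0.44) and 0.05 (-0.26 to 0.37). A p that misses the threshold does not show that they act alike, and over all genes these intervals reached a median of 0.31 to either side. Camera called 9 lists in these pairs at the preset correlation. For VSGC12 against VSG22 they were interferon (-0.12), lipid handling (-0.13) and cell cycle (-0.17; adjusted p = 0.87 with an estimated correlation for each). For FF against VSG22 they were glycolysis (0.15) and cell cycle (-0.16; adjusted p = 0.79 with an estimated correlation). For VSGC12 against FF they were phagocytic genes (-0.25), cytokines (-0.14), glycolysis (-0.11) and oxidative stress (-0.10; adjusted p = 0.78 with an estimated correlation). Single arrays moved the counts here too. Between VSGC12 and FF there were 57 and 103 genes without FF replicate 1 and replicate 2, 50 and 39 without VSGC12 replicate 1 and replicate 2, 2 without any 1 of the Dex or VSG22 arrays, and 0 without EtoH replicate 2. Between VSGC12 and VSG22 there were 40 without VSG22 replicate 1, 30 and 9 without VSGC12 replicate 1 and replicate 2, and 1 without either Dex array. Between FF and VSG22 there were 54 and 114 without FF replicate 1 and replicate 2, 48 and 18 without VSG22 replicate 1 and replicate 2, and 5 and 7 without Dex replicate 1 and replicate 2. The moderated F-test over all 4 called 47 genes (2431 at an unadjusted p under 0.05), and 21 with a replicate block. The count was 8 without either EtoH array, 984 and 665 without Dex replicate 1 and replicate 2, 14 and 0 without FF replicate 1 and replicate 2, 5 without VSG22 replicate 2, and 23 and 21 without VSGC12 replicate 1 and replicate 2.

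The responses of the 4 glucocorticoids ran in the same direction, and differences in their overall size depended on the processing. Over the 3874 genes called higher for the mean with complete values, the mean shift from EtoH was 0.72 ± 0.05 in Dex, 0.79 ± 0.02 in FF, 0.75 ± 0.03 in VSG22 and 0.78 ± 0.03 in VSGC12 (SD, n = 2). Over the 4065 called lower it was -0.62 ± 0.09, -0.73 ± 0.02, -0.64 ± 0.01 and -0.71 ± 0.05. Dex minus the mean of the other 3 was -0.05 (95% interval -0.115 to 0.015) for the first set and 0.069 (-0.025 to 0.163) for the second. For FF minus Dex the differences were 0.065 (-0.014 to 0.145; 0.113 on slide 1 and 0.018 on slide 2) and -0.102 (-0.218 to 0.013; -0.148 and -0.057). For VSG22 minus Dex they were 0.026 (-0.053 to 0.106; 0.081 and -0.029) and -0.017 (-0.133 to 0.098; -0.085 and 0.051), so the sign differed between slides. For VSGC12 minus Dex they were 0.058 (-0.022 to 0.137; 0.117 and -0.001) and -0.088 (-0.203 to 0.028; -0.116 and -0.059). Among the others they lay between -0.008 and 0.039 for the first set and between -0.085 and 0.015 for the second, and each interval held 0. Fry's adjusted p was 0.26 or more in each pair. Under alternatives, the interval of Dex minus the other 3 excluded 0 for the first set with quantile normalization (-0.069), no filter (-0.111), trend and robust eBayes (-0.067), a percentile over detected probes (-0.08) and without probes in patches (-0.069). It did so for the second set with quantile normalization and cyclic loess (0.076) and without Dex replicate 2 (0.105, and 0.104 with the gene set held fixed). Without Dex replicate 1, this difference was 0.398 for the first set (0.205 with the gene set held fixed), opposite in sign to the main value. Without Dex replicate 2 it was 0.171, and -0.071 with the gene set held fixed, each with an interval that excluded 0. In that last setting 10 of the 14 intervals for differences between glucocorticoids came to exclude 0. For the first set the interval also excluded 0 without any 1 array of the other groups (-0.071 to -0.133). With 1 array left in a glucocorticoid group, the choice of genes favours a larger response in that group. The values without a glucocorticoid array therefore cannot tell a difference in response size from the choice of genes. Across genes, which are not independent replicates, the log2 changes of 2 glucocorticoids correlated with r from 0.741 (Dex and VSG22) to 0.916 (FF and VSGC12), and Spearman's rho from 0.784 to 0.91. Because both share the EtoH arrays, unchanged groups gave r of 0.499 to 0.503 on average in 100 simulations, with a highest value of 0.55. Without Dex replicate 2, r fell to 0.509 for Dex and FF and 0.543 for Dex and VSG22 (0.709 and 0.746 with the gene set held fixed), and without Dex replicate 1 to 0.527 for Dex and VSG22 (0.646). The values of 0.509 and 0.527 lie below the highest simulated value of their own pairs (0.544 for Dex and FF, 0.54 for Dex and VSG22). The 0.543 for Dex and VSG22 lies just above 0.54. However, the simulations had 2 arrays per group and none was run for 1. FF and VSGC12 both raised 2681 genes and lowered 2834, a count that the shared EtoH arrays alone would raise and that was not simulated.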

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

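The tests on local patches of signal, on the interferon list and on the signal scale of the EtoH arrays, with their setting of quantile normalization and cyclic loess, were chosen only after the result was seen, though the bounds for the last were set before its own count was known. Differences between glucocorticoids passed limma's test for 67 genes between FF and Dex, 99 between VSG22 and Dex, 71 between VSGC12 and Dex, 1 between VSGC12 and FF, and 47 in the F-test over the 4. With a replicate block these counts were 31, 118, 48, 0 and 21. Outside the main measurement, spots that were not well above background on any array of the other groups but were on a Dex array lay close together: 82% of them on Dex replicate 1 and 79.3% on replicate 2 had another within 2 spots. Random placement gave 23.4% and 34.8% on average. The arrays of other groups lay between 33.2% and 65.8%, where random placement gave 6.3% to 23.7% on average. Every array lay above the highest of its own 100 random placements, so such closeness was not particular to Dex. On FF replicate 1 the share was 65.8% against 16.8%. The spike-in controls, RNA added in known amounts, gave a slope of signal on amount of at most 0.853 on the EtoH arrays and at least 0.904 on the glucocorticoid arrays.

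Some genes called higher in Dex than in another glucocorticoid may owe this to local signal on the slides. There were 79 such genes, of which 41 were not well above background in any of the other 3 glucocorticoid groups. Of these 41, 33 (80.5%) have a probe in a patch on a Dex array, and 40 were dim in EtoH as well. They are the kind of spot from which the patches were defined: of 21 genes as dim in the other 3 groups and well above background on both Dex arrays, but not called, 12 (57.1%) lie in a patch too. Local signal and an effect of Dex therefore cannot be told apart for the 41. The 40 that were dim in EtoH as well passed the filter only through Dex. The filter therefore favours genes higher in Dex among those called. Without probes in patches, 6 genes differed between FF and Dex, 25 between VSG22 and Dex and 24 between VSGC12 and Dex. Of the 67, 99 and 71 called before, 30, 55 and 33 could still be tested and 5, 24 and 23 were called, so calls were lost outside patches too and these counts do not bear on the explanation. An effect of Dex on the genes outside patches stays open and was not tested.

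At camera's preset correlation, but not with an estimated one, the interferon genes as a list were lowered less by Dex than by FF, VSG22 and VSGC12, with 4, 4 and 5 of 36 genes called singly. The difference was 0.357 in the mean shift of the type I interferon list, Dex minus the other 3 (95% interval 0.237 to 0.477; 0.382 on slide 1 and 0.332 on slide 2). The tables argue against patches as the whole cause (0.317, 0.212 to 0.422, without probes in patches), against 1 deviating Dex array (0.342, 0.198 to 0.487, without Dex replicate 1, and 0.416 without replicate 2) and against a different signal scale (0.358, 0.302 to 0.413, after quantile normalization and cyclic loess). With the gene set held fixed, leaving out Dex replicate 1 gave 0.299 (0.152 to 0.446), and subtracting the array median gave 0.319 with an interval that includes 0 (-0.109 to 0.748). This pattern came from 132 tests of lists in pairs. It replaced an earlier one, a smaller mean response to Dex over all genes called higher (-0.05, 95% interval -0.115 to 0.015). That one depended on the setting, with -0.111 with no filter, and 0.398 without Dex replicate 1, where the choice of genes favours Dex. The pattern was not particular to interferon genes. The cell cycle list was raised less by Dex too, with Dex minus the other 3 at -0.339 on slide 1 and -0.236 on slide 2. A weaker effect of Dex on interferon genes at 100 nM is therefore only a hypothesis, and a difference in dose response was not tested.

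The large share of genes called between the glucocorticoids and EtoH, 44.2%, with cell cycle genes up and interferon genes down, could in part come from a narrower signal scale on the EtoH arrays, where the spike-in slope averaged 0.851 against 0.93. After quantile normalization and cyclic loess, 8346 of 17913 genes were called, against 7961 of 18030 before. Of these, 7303 (87.5%) had been called before in the same direction, short of the 90% set before this count was known. The cell cycle and interferon lists were as large (1.81 and -0.99). The count did not fall, but with the agreement short of its bound the test cannot tell whether the scale is a source of this share. For the genes not called both times, the scale of the EtoH arrays and an effect of the glucocorticoids cannot be told apart.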

How the results depend on the processing

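The settings without probes in patches, with a percentile over probes well above background on all arrays, with quantile normalization plus cyclic loess, without both Dex arrays, and without a Dex array but with the genes of the full filter were chosen only after the result was seen; the other alternatives were chosen before the data were examined, and each was run. On the mean of the 4 glucocorticoids against EtoH, 8 lists kept their direction and call under every setting except the estimated correlation. Their means over the processing alternatives ran from 1.58 to 1.92 for cell cycle, -1.06 to -0.85 for interferon, -1.29 to -0.81 for cytokines, -0.65 to -0.38 for chemokines, 0.37 to 0.56 for sterol synthesis, -0.53 to -0.31 for osteoclast genes, -1.10 to -0.80 for circadian clock and 0.21 to 0.41 for the respiratory chain. Lists not called before passed the threshold 23 times, for 8 combinations of a list and a comparison. The comparisons were the mean against EtoH and the 3 pairs with Dex. Of 141 named genes called on the mean contrast, 112 were called in the same direction under every setting that tested them; of 11 not called, 6 were called under none. Of 205 results on named genes, those with the same direction and call numbered 192 with normexp, 202 with quantile normalization, 170 with the array median, 156 with no filter, 137 of 150 with the filter over all 10 arrays, 200 with the mean of probes, 194 with the replicate block, 198 with trend and robust eBayes, 151 of 164 without patches, 199 with a percentile over detected probes 196 of 201 with cyclic loess and 160 to 199 with 1 array left out; where fewer than 205 could be tested, a filter or missing signal removed the others. Subtracting the array median moved the median of all genes from -0.005 to 0.118 on the mean contrast, and its values include that shift. Signal over background limits detection, since 40.1% to 44.4% of spots on an array were well above background. Tests of lists for a single glucocorticoid and among FF, VSG22 and VSGC12 were run in the main processing only. Correlations are over genes complete for each pair, so they differ slightly from those given above. For each setting below, only results that moved beyond a bound are listed. For r the bound was its SD between slides, from 0.008 for Dex and VSGC12 to 0.081 for Dex and VSG22. An unlisted r can therefore have changed more than a listed one. For counts it was a set ratio, and for mean shifts from EtoH the spread within groups. Where 1 array is left out, its group keeps a lone sample, assumed to vary like the other groups. Values in parentheses are mean log2 changes of a list or of a gene.

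With normexp correction (offset 50), genes called numbered 118 for VSGC12 and Dex and 27 for the F-test. List calls lost were phagocytic genes (-0.08) and lipid handling (-0.08) for VSGC12 against Dex. Mean shifts from EtoH moved to 0.61, 0.68, 0.63 and 0.67 in Dex, FF, VSG22 and VSGC12 over the genes called higher and to -0.50, -0.58, -0.52 and -0.55 in Dex, FF, VSG22 and VSGC12 over the genes called lower. R moved to 0.805 for Dex and VSGC12, 0.863 for FF and VSG22, 0.949 for FF and VSGC12 and 0.847 for the mean of the 6; the cause was not tested. With quantile normalization, genes called numbered 153 for VSG22 and Dex, 1 for VSGC12 and VSG22 and 1 for FF and VSG22. Lost calls of lists were glycolysis (-0.04) for VSG22 against Dex, and lipid handling (-0.04) and unfolded protein stress (-0.08) for VSGC12 against Dex. Intervals of the difference in mean shift came to exclude 0: over the genes called higher, -0.069 for Dex minus the other 3, 0.074 for FF against Dex, 0.056 for VSG22 against Dex and 0.077 for VSGC12 against Dex; the cause was not tested. With median subtraction, genes called numbered 2043 for Dex against EtoH, 2497 for FF against EtoH, 1806 for VSG22 against EtoH, 2364 for VSGC12 against EtoH, 3763 for the mean of the 4, 128 for FF and Dex, 241 for VSG22 and Dex, 112 for VSGC12 and Dex, 11 for VSGC12 and VSG22, 34 for FF and VSG22, 15 for VSGC12 and FF and 163 for the F-test. 2 lists for VSG22 against Dex passed the threshold. List calls lost were antigen presentation (-0.13) for FF against Dex, and cytokines (-0.12), chemokines (-0.18) and glycolysis (-0.09) for VSG22 against Dex, and lipid handling (0) and unfolded protein stress (-0.03) for VSGC12 against Dex. Mean shifts from EtoH moved to 1.17, 1.24, 1.08 and 1.24 in Dex, FF, VSG22 and VSGC12 over the genes called higher and to -1.07, -1.21, -1.11 and -1.15 in Dex, FF, VSG22 and VSGC12 over the genes called lower. Genes called higher and lower by both numbered 1039 and 447 for Dex and FF, 769 and 401 for Dex and VSG22, 963 and 429 for Dex and VSGC12, 991 and 501 for FF and VSG22, 1315 and 555 for FF and VSGC12 and 1101 and 491 for VSG22 and VSGC12; the cause was not tested. With no filter on dim probes, genes called numbered 2369 for Dex against EtoH, 3327 for FF against EtoH, 2719 for VSG22 against EtoH, 3102 for VSGC12 against EtoH, 4935 for the mean of the 4, 3 for FF and Dex, 5 for VSG22 and Dex, 5 for VSGC12 and Dex, 0 for VSGC12 and FF and 0 for the F-test. Lost calls of lists were antigen presentation (-0.14) for FF against Dex, and chemokines (-0.11) and glycolysis (-0.12) for VSG22 against Dex. Intervals of the difference in mean shift came to exclude 0: over the genes called higher, -0.111 for Dex minus the other 3, 0.109 for FF against Dex, 0.111 for VSG22 against Dex and 0.113 for VSGC12 against Dex, and over the genes called lower, -0.134 for FF against Dex. Shifts from EtoH moved to 0.88, 0.99, 0.99 and 0.99 in Dex, FF, VSG22 and VSGC12 over the genes called higher and to -0.84, -0.98, -0.88 and -0.94 in Dex, FF, VSG22 and VSGC12 over the genes called lower. R moved to 0.666 for Dex and FF, 0.622 for Dex and VSG22, 0.692 for Dex and VSGC12, 0.741 for FF and VSG22, 0.771 for FF and VSGC12, 0.77 for VSG22 and VSGC12 and 0.71 for the mean of the 6. Genes called higher and lower by both numbered 1022 and 895 for Dex and FF, 973 and 754 for Dex and VSG22, 1008 and 835 for Dex and VSGC12, 1212 and 1044 for FF and VSG22, 1332 and 1269 for FF and VSGC12 and 1251 and 997 for VSG22 and VSGC12. The sign turned for Pik3c2g in Dex (-0.25) and in VSGC12 (-0.03), where another probe then represented the gene. More genes were tested by construction, and the cause of the other changes was not tested further. With the filter over all 10 arrays, genes called numbered 0 for FF and Dex, 5 for VSG22 and Dex, 18 for VSGC12 and Dex and 1 for the F-test. Mean shifts from EtoH moved to 0.63, 0.71, 0.66 and 0.70 in Dex, FF, VSG22 and VSGC12 over the genes called higher and to -0.54, -0.65, -0.57 and -0.62 in Dex, FF, VSG22 and VSGC12 over the genes called lower. R moved to 0.894 for Dex and FF, 0.872 for Dex and VSGC12, 0.88 for FF and VSG22, 0.951 for FF and VSGC12 and 0.883 for the mean of the 6; fewer genes were tested by construction, and the cause was not tested further. With the mean of a gene's probes, genes called numbered 0 for VSGC12 and FF. Lost calls of lists were lipid handling (-0.06) and osteoclast genes (-0.19) for VSGC12 against Dex. The sign turned for Ywhaz (-0.02); the cause was not tested. With a replicate block, genes called numbered 31 for FF and Dex, 0 for VSGC12 and FF and 21 for the F-test. List calls lost were unfolded protein stress (-0.11) for VSGC12 against Dex; the cause was not tested. With trend and robust eBayes, genes called numbered 228 for VSG22 and Dex and 1 for VSGC12 and VSG22. Intervals of the difference in mean shift came to exclude 0: over the genes called higher, -0.067 for Dex minus the other 3. Shifts from EtoH moved to 0.67 and 0.75 in Dex and FF over the genes called higher; the cause was not tested. With only the groups compared, genes called numbered 2072 for Dex against EtoH, 0 for FF and Dex, 0 for VSG22 and Dex, 0 for VSGC12 and Dex and 0 for VSGC12 and FF; fewer samples gave the spread by construction. With an estimated correlation, 0 lists for the mean, 0 lists for FF against Dex, 0 lists for VSG22 against Dex and 0 lists for VSGC12 against Dex passed the threshold. Lost calls of lists were cytokines (-1.10), chemokines (-0.58), interferon (-0.97), MAP kinase phosphatases (-0.53), sterol synthesis (0.44), cell cycle (1.80), osteoclast genes (-0.43), circadian clock (-1.03) and respiratory chain (0.29) for the mean of the 4, and interferon (-0.37), antigen presentation (-0.14) and cell cycle (0.24) for FF against Dex, and cytokines (-0.15), chemokines (-0.21), interferon (-0.29), glycolysis (-0.12) and cell cycle (0.40) for VSG22 against Dex, and phagocytic genes (-0.25), cytokines (-0.25), chemokines (-0.27), interferon (-0.41), lipid handling (-0.08), cell cycle (0.23), osteoclast genes (-0.28) and unfolded protein stress (-0.11) for VSGC12 against Dex; only the correlation between genes changed by construction. With probes in patches left out, genes called numbered 6 for FF and Dex, 25 for VSG22 and Dex, 24 for VSGC12 and Dex, 1 for FF and VSG22 and 4 for the F-test. 5 lists for VSGC12 against Dex passed the threshold. List calls lost were MAP kinase phosphatases (-0.41) for the mean of the 4, and cytokines (-0.11) for VSG22 against Dex, and phagocytic genes (-0.14), cytokines (-0.25) and lipid handling (-0.06) for VSGC12 against Dex. Intervals of the difference in mean shift came to exclude 0: over the genes called higher, -0.069 for Dex minus the other 3 and 0.083 for FF against Dex. R moved to 0.847 for Dex and VSGC12 and 0.858 for the mean of the 6. It also rose from 0.817 to 0.853 for Dex and FF and from 0.739 to 0.775 for Dex and VSG22. Those 2 changes are within the wider SD between slides of these pairs (0.059 and 0.081). The cause was not tested. With a percentile over detected probes, intervals of the difference in mean shift came to exclude 0: over the genes called higher, -0.08 for Dex minus the other 3, 0.088 for FF against Dex, 0.067 for VSG22 against Dex, 0.085 for VSGC12 against Dex, 0.019 for VSGC12 against VSG22 and 0.021 for FF against VSG22; the cause was not tested. With quantile normalization plus cyclic loess, genes called numbered 179 for VSG22 and Dex, 1 for VSGC12 and VSG22, 1 for FF and VSG22 and 72 for the F-test. List calls lost were glycolysis (-0.09) for VSG22 against Dex. Intervals of the difference in mean shift came to exclude 0: over the genes called lower, 0.076 for Dex minus the other 3, -0.093 for FF against Dex and -0.087 for VSGC12 against Dex. Mean shifts from EtoH moved to -0.56, -0.65 and -0.65 in Dex, FF and VSGC12 over the genes called lower. R moved to 0.863 for FF and VSG22 and 0.847 for the mean of the 6; the cause was not tested. With both Dex arrays left out, list calls lost were MAP kinase phosphatases (-0.57) for the mean of the 4; the cause was not tested.

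Leaving out 1 array at a time, genes called ranged from 3131 to 6767 for Dex against EtoH, 3934 to 7582 for FF against EtoH, 2982 to 5945 for VSG22 against EtoH, 3783 to 7164 for VSGC12 against EtoH and 4734 to 8954 for the mean of the 4. Between glucocorticoids they ranged from 22 to 880 for FF and Dex, 10 to 1856 for VSG22 and Dex, 5 to 1233 for VSGC12 and Dex, 0 to 40 for VSGC12 and VSG22, 0 to 114 for FF and VSG22, 0 to 103 for VSGC12 and FF and 0 to 984 for the F-test. Lists called ranged from 2 to 5 for VSG22 against Dex and 2 to 10 for VSGC12 against Dex. List means for the mean of the 4 ranged from -0.57 to -0.49 for MAP kinase phosphatases. List means for FF against Dex ranged from -0.19 to -0.13 for antigen presentation. List means for VSG22 against Dex ranged from -0.23 to -0.06 for cytokines, -0.26 to -0.05 for chemokines and -0.16 to -0.08 for glycolysis. List means for VSGC12 against Dex ranged from -0.36 to -0.14 for phagocytic genes, -0.34 to -0.17 for cytokines, -0.34 to -0.20 for chemokines, -0.15 to 0 for lipid handling, -0.35 to -0.20 for osteoclast genes and -0.20 to -0.02 for unfolded protein stress. Over the genes called higher, differences in mean shift ranged from -0.133 to 0.398 for Dex minus the other 3, -0.334 to 0.2 for FF against Dex, -0.479 to 0.138 for VSG22 against Dex, -0.38 to 0.145 for VSGC12 against Dex, -0.044 to 0.099 for VSGC12 against VSG22, -0.046 to 0.153 for FF against VSG22 and -0.122 to 0.07 for VSGC12 against FF. Over the genes called lower, differences in mean shift ranged from -0.02 to 0.112 for Dex minus the other 3, -0.149 to -0.012 for FF against Dex, -0.068 to 0.075 for VSG22 against Dex, -0.139 to -0.002 for VSGC12 against Dex, -0.119 to -0.044 for VSGC12 against VSG22, -0.106 to -0.076 for FF against VSG22 and -0.035 to 0.043 for VSGC12 against FF, so signs turned there too, for Dex minus the other 3, VSG22 against Dex and VSGC12 against FF. Mean shifts from EtoH over the genes called higher ranged from 0.70 to 1.14 for Dex, 0.77 to 0.97 for FF, 0.66 to 0.98 for VSG22 and 0.75 to 0.97 for VSGC12. Mean shifts from EtoH over the genes called lower ranged from -0.95 to -0.59 for Dex, -1.06 to -0.70 for FF, -0.98 to -0.61 for VSG22 and -1.04 to -0.69 for VSGC12. The correlations ranged from 0.509 to 0.85 for Dex and FF, 0.527 to 0.795 for Dex and VSG22, 0.573 to 0.849 for Dex and VSGC12, 0.717 to 0.876 for FF and VSG22, 0.785 to 0.928 for FF and VSGC12, 0.764 to 0.907 for VSG22 and VSGC12 and 0.711 to 0.865 for the mean of the 6. Genes called higher by both ranged from 1388 to 2650 for Dex and FF, 1339 to 2046 for Dex and VSG22, 1382 to 2360 for Dex and VSGC12, 1467 to 2569 for FF and VSG22, 1641 to 3100 for FF and VSGC12 and 1478 to 2660 for VSG22 and VSGC12. Genes called lower by both ranged from 1269 to 2411 for Dex and FF, 1096 to 1975 for Dex and VSG22, 1202 to 2336 for Dex and VSGC12, 1252 to 2538 for FF and VSG22, 1582 to 3084 for FF and VSGC12 and 1237 to 2498 for VSG22 and VSGC12. The differences in mean shift over the genes called higher turned in sign without Dex replicate 1 (0.398, -0.334, -0.479, -0.38), without Dex replicate 2 (0.171, -0.139, -0.221, -0.153) and without Dex replicate 1 with the genes of the full filter (0.205, -0.134, -0.287, -0.194), for Dex minus the other 3, FF against Dex, VSG22 against Dex and VSGC12 against Dex in turn; the cause was not tested. Without Dex replicate 2 but with the genes of the full filter they kept their sign (-0.071, 0.112, 0.02, 0.08). With 1 Dex array left, the choice of genes favours a larger response to Dex, so these values do not show its size.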

Other observations

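All tests here were chosen only after the main results were seen: 16 gene families, picked by symbol, were tested with camera on the mean of the 4 glucocorticoids against EtoH, adjusted over the 16, and each call was lost with an estimated correlation. Families of cell division and of protein synthesis in mitochondria were higher. Picking by symbol alone can bring in other genes, such as pseudogenes. Of 20 centromere protein genes, which build the site of chromosome attachment, 16 rose and 0 fell (median log2 1.07, adjusted p = 2.4e-08; adjusted p = 0.25 with an estimated correlation). Of 10 Fanconi anaemia genes, which repair DNA crosslinks, 6 rose and 1 fell (0.65, adjusted p = 0.002; adjusted p = 0.3 with an estimated correlation). Of 79 mitochondrial ribosomal protein genes, 41 rose and 3 fell (0.23, adjusted p = 1e-06; adjusted p = 0.44 with an estimated correlation). Of 17 aminoacyl-tRNA synthetase genes, mostly mitochondrial ones, 8 rose and 1 fell (0.26, adjusted p = 0.017; adjusted p = 0.4 with an estimated correlation).

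Families of host defence and of vesicle traffic were lower. Of 15 genes for guanylate-binding proteins and immunity-related GTPases, which are interferon-induced, 9 fell and 0 rose (-0.54, adjusted p = 0.002; adjusted p = 0.3 with an estimated correlation). Of 45 RAB GTPase genes, which direct membrane traffic, 24 fell and 6 rose (-0.22, adjusted p = 0.0055; adjusted p = 0.55 with an estimated correlation). Of 17 genes for the vacuolar proton pump, which acidifies lysosomes, 8 fell and 1 rose (-0.28, adjusted p = 0.045; adjusted p = 0.3 with an estimated correlation). The medians of these called families kept their sign under the main processing and all alternative scalings, but the counts of genes called changed. With the array median subtracted, RAB GTPase genes had 1 higher and 3 lower and proton pump genes 1 and 1. The others then had 14 and 0 (centromere), 5 and 0 (Fanconi), 17 and 0 (mitochondrial ribosome), 6 and 0 (synthetases) and 0 and 6 (guanylate-binding). Not called were symbol groups for histones, ribosomal proteins (adjusted p = 0.48 each) and the proteasome (adjusted p = 0.23), whose counts are not given since the symbols also took in other genes. Not called either were kinesins (12 rose, 5 fell; adjusted p = 0.079), cathepsins (2 and 4; 0.23) and Schlafen genes (0 and 2; 0.26). Nor were serpins (4 and 7; 0.48), collagens (4 and 3; 0.73) and solute carriers (51 and 59; 0.79). Among these, the medians of kinesins, collagens and solute carriers, and of the proteasome and ribosomal symbol groups, changed sign with the scaling.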
